A study of Mus musculus with 16 samples.

How the data were processed

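Cortical brain tissue from 16 mice, 8 to 9 months of age, was profiled by 3' mRNA sequencing. The labels give 4 genotypes with 4 mice each, 2 females and 2 males per genotype, on a strain labelled C57BL/6; C3. Control mice carried no tau transgene and both Trem2 alleles (TREM2+/+). The other mice carried the P301S tau transgene, a mutant form of the microtubule-binding protein tau, with both Trem2 alleles (P301S+ TREM2+/+), with 1 allele (P301S+ TREM2+/-, here the heterozygotes) or with none (P301S+ TREM2-/-, here the knockouts). Trem2 encodes a lipid-sensing receptor of microglia, the resident macrophages of the brain, and signals through the adapter Tyrobp. Groups were taken from the sample descriptions and sex from the gender label. Mice were numbered consecutively by genotype, and no batch, litter or preparation day was given, so that a batch that followed this order could not be told apart from genotype.

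Total RNA was extracted on RNeasy columns and made into libraries with the Lexogen QuantSeq 3' kit, which primes at the poly(A) tail and reads 1 short stretch near the 3' end of each transcript. The libraries were sequenced on a HiSeq4000, per the labels' protocols. STAR, HTSeq, edgeR and limma are named as tools and mm10 as the genome build, per the submitters' processing notes, without versions, roles or order. The deposited values are RPKM (reads per kilobase of gene and per 1e+06 reads), per the file headers. Dividing by gene length does not suit reads that come from 3' ends, so RPKM was compared between libraries for the same gene and not between genes. Whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and genes with near-identical copies, such as those of the H2 family, are uncertain in level.

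Each file lists 24060 genes, of which 18911 were above 0 in at least 1 library. Within a gene, RPKM values were whole multiples of the value of 1 read, and whole reads were recovered for 100.0% of the genes above 0, with a tolerance of 1e-05 reads or a relative 3e-07. The recovered reads summed to 100.0% of the total implied by each library. They ranged from 2.55 to 14.47 M per library, where M stands for 1e+06 reads. 1 line per file named no gene and was left out, and 2 symbols were listed more than once. No 2 libraries were identical, and the lowest chi-square per gene between libraries of 1 genotype was 6.87 over genes with at least 20 reads, so every library was counted as a separate mouse. PCR reads without molecular identifiers are not independent molecules, so read numbers bound counting error only.

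The plan made before the data were examined assumed raw counts. Because the files hold RPKM, differential expression was tested with limma 3.58.1 in R 4.3.3 (trend on) on log2(RPKM + 1), for the 12015 genes with a mean RPKM of at least 1. The model held the 4 genotypes and sex as an additive covariate over all 16 libraries (11 residual degrees of freedom). Fold changes are therefore on the log2(RPKM + 1) scale, which understates the change of low genes. Adjusted p-values are Benjamini-Hochberg values from limma over all genes tested, with a threshold of 0.05. The 7 comparisons were the P301S effect (P301S+ TREM2+/+ against control), partial loss (heterozygotes against P301S+ TREM2+/+), complete loss (knockouts against P301S+ TREM2+/+), complete against partial loss, the departure of the heterozygotes from the midpoint of P301S+ TREM2+/+ and knockouts, and partial and complete loss each against control. Differences between the sexes in the first 4 were tested as an interaction, with 8 residual degrees of freedom.

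Gene lists (27 lists, 378 genes) were fixed before the data were examined, from general knowledge of brain cell types, Trem2 and tau mice, with Trem2 itself left out. They were homeostatic microglia, disease-associated microglia, pan-microglia and macrophage, complement, interferon response, antigen presentation, inflammatory cytokine and NF-kB, reactive astrocyte, astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, excitatory neuron, inhibitory neuron, synapse, immediate early, endothelium and mural cell, heat shock and unfolded protein, lysosome, cholesterol and lipid handling, mitochondrial respiratory chain, proliferation, and, for tissue or cells that a cortical dissection could hold by accident, choroid plexus, meninges and fibroblast, striatum, hippocampus, blood and T cell. 4 list genes were not found in the files and 67 lay below the filter. The T cell list had only Cd4 left and was not tested with this filter. Lists were tested against all other genes with camera from limma at a preset correlation of 0.01, adjusted over the 26 tested lists within a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction, were run beside it. List means per library were compared between pairs of genotypes by two-sided exact permutation tests, whose smallest p with 4 against 4 mice is 0.029.

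Named genes followed a rule fixed in advance. It took Trem2, Tyrobp, Treml1, Treml2, Treml4, Mapt and Prnp in every comparison; the called genes with the largest changes and no overlap of libraries; called list members; where fewer than 10 genes were called, the 10 genes with the smallest p, as values only; and up to 2 highly expressed examples of each list without a called member. Genes outside this rule were chosen after their values were seen. They are Cst7, Clec7a, Gfap and C4b, list members that passed when adjusted over the list alone, genes called only without control replicate 3, and Lyz2, Oard1 and Flywch1 in comparisons where the rule does not take them. Some genes that the rule takes are not reported here. Gene positions are from GENCODE vM21 on GRCm38, the same assembly as mm10.

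Alternatives tried were median-ratio size factors, limma-voom on the recovered reads, no filter, a stricter filter, no sex covariate, only the genotypes compared, an adjusted p threshold of 0.1, leaving out each mouse in turn, genes outside the chromosome of Trem2, list members unique to 1 list, and, added after the data had been seen, pseudocounts of 0.1 and 0.5, array weights, the joint removal of control replicate 3 and both P301S+ TREM2+/+ females, which lay farthest out on the first and second principal components, voom with quality weights, and 2 covariates for hidden structure. The procedures were tested on simulated data with 200 changed genes. At a log2 change of 1, 56% were recovered for the P301S effect and 56% for complete loss, and at a log2 change of 2, 96% and 88%, with 7 and 6 false calls among 12015 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, read recovery and plots. Count models were not used as the main test because the deposited values are normalized, although the recovered reads would have allowed them.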

Results

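The series comprised 16 cortical transcriptomes from male and female mice of 8 to 9 months, 4 per genotype, and asked how the loss of 1 or of both Trem2 alleles alters the cortex of mice with tau pathology. Read depth was 8.26 ± 4.24 M reads (M, 1e+06) in controls, 8.00 ± 3.26 M in P301S+ TREM2+/+ mice, 9.30 ± 1.96 M in heterozygotes and 5.94 ± 2.68 M in knockouts (mean ± SD, n = 4 each), and no pair of genotypes differed in depth (exact permutation p from 0.086 to 0.8). The shallowest library, knockout replicate 2, held 2.55 M reads. Xist, the transcript of the inactive X chromosome, and Ddx3y, on the Y chromosome, matched the labelled sex in all 16 libraries. Xist was higher in heterozygote replicate 3 than in the other males, as given under Other observations.

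Trem2 (chromosome 17, 48346401 to 48354147, plus strand, GRCm38) followed the labelled genotype. Its level was 27 ± 8.69 RPKM in P301S+ TREM2+/+ mice, 12.9 ± 8.98 in heterozygotes, 2.09 ± 1.11 in knockouts and 12.4 ± 5.53 in controls (SD, n = 4 each). The 4 knockouts lay between 1.44 and 3.75 RPKM, from 5 to 29 reads each, below every library of the other genotypes. The labels do not say which part of the gene was deleted, and 3' reads from outside that part would still be counted. Relative to Tyrobp, the signalling adapter of the receptor, Trem2 stood at 0.29 to 0.36 in P301S+ TREM2+/+ libraries, 0.13 to 0.21 in heterozygotes and 0.033 to 0.077 in knockouts, and at 0.27 to 0.42 in controls except for control replicate 3 at 1.4.

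**Figure D1:**
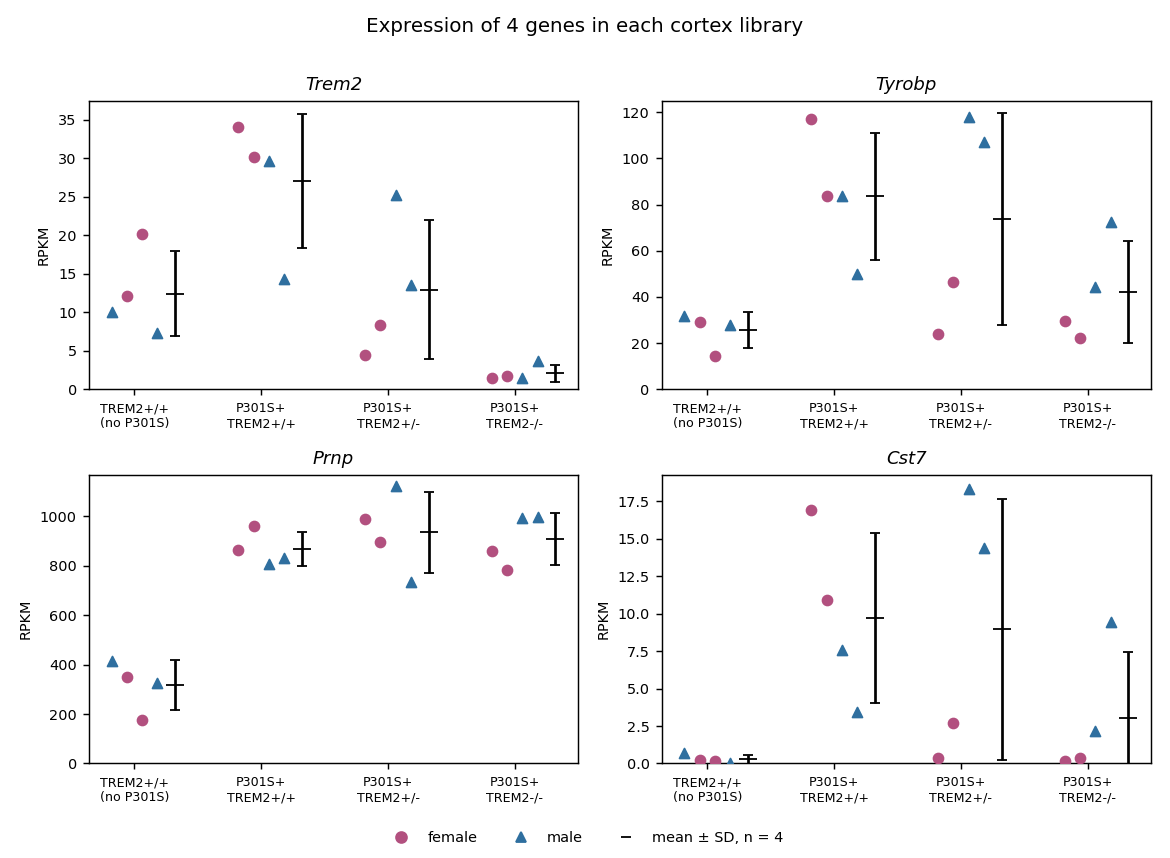
RPKM of Trem2, Tyrobp, Prnp and Cst7 in each of the 16 libraries, by genotype and sex, with the mean ± SD of 4 mice. Trem2 lies between 1.44 and 3.75 RPKM in the knockouts, and Prnp averages 316 RPKM in controls against 866, 934 and 907 in the 3 tau genotypes.

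Control replicate 3, a female, stood apart on the first principal component, and both P301S+ TREM2+/+ females on the second. Control replicate 3 had a score of -130.8 on the first principal component, which held 52.4% of the variance, and no other library lay below -18.8. On the second component (14.6% of the variance) the P301S+ TREM2+/+ females lay at -45 and -41.3 and no other library below -12.5. In control replicate 3 the top 50 genes took 18.6% of reads, the precursor of ribosomal RNA Rn45s took 4.45%, and small nucleolar RNA genes gave 758.6 reads per 1e+06 reads against 20.3 to 67.2 elsewhere. Psap, the precursor of lysosomal saposins, was at 10.5 RPKM there and at 640 to 886 in the other controls. This library entered the control mean and, through the shared spread, the tests between tau genotypes as well, and counts without it are given for each comparison.

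**Figure D2:**
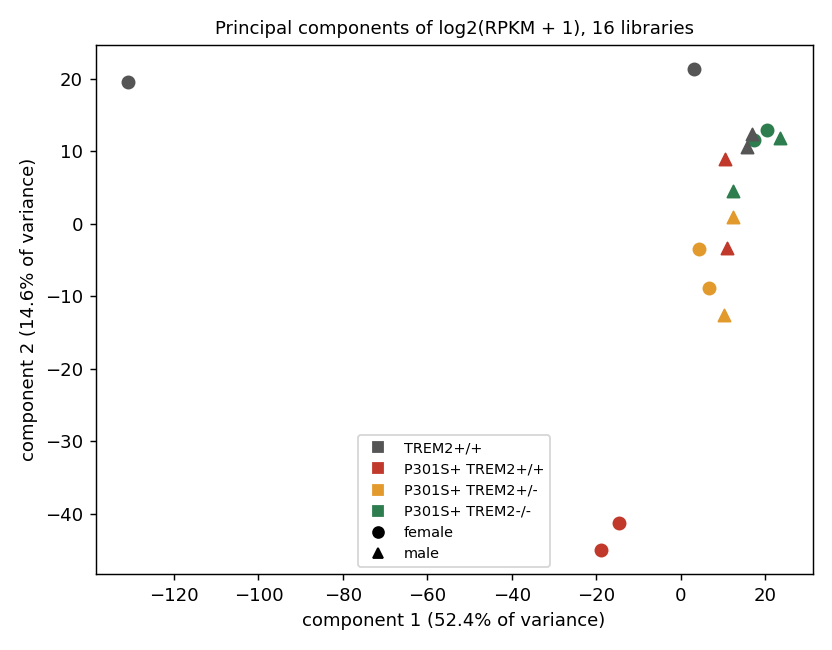
Scores of the 16 libraries on the first and second principal components of log2(RPKM + 1), by genotype and sex, which hold 52.4% and 14.6% of the variance. Control replicate 3 lies at -130.8 on the first component.

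The P301S effect compares tau mice that keep both Trem2 alleles with controls. Genes of activated microglia, antigen presentation, lysosomes and myelin stood higher as groups in the tau mice, and genes of excitatory neurons lower, although none of these lists passed with an estimated correlation (adjusted p from 0.47 to 0.62). Among disease-associated microglia genes, the cysteine protease inhibitor Cst7 was at 9.72 ± 5.7 RPKM in P301S+ TREM2+/+ mice and 0.272 ± 0.291 in controls (SD, n = 4 each), and the antibacterial enzyme Lyz2 at 14.6 ± 5.18 and 2.35 ± 1.58. Tyrobp was at 83.5 ± 27.4 and 25.8 ± 7.73 RPKM, a log2 difference of 1.65 (SE 0.41, limma adjusted p = 0.265). Prnp, the prion protein gene (chromosome 2, 131909928 to 131938429), was at 866 ± 68 against 316 ± 102 RPKM, a log2 difference of 1.52 (SE 0.24, adjusted p = 0.171), the smallest adjusted p of this comparison. Tau transgenes are often carried by the prion gene's vector, so reads of the transgene could be counted there. Mapt, the mouse tau gene (chromosome 11, 104231390 to 104332090), was at 103 ± 15.3 against 130 ± 41.1 RPKM (log2 difference -0.29, adjusted p = 0.454).

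No gene passed limma's test of the P301S effect, although 1657 had an unadjusted p under 0.05, and limma-voom on the recovered reads called 0. Array weights, which weighted control replicate 3 at 0.04 and the other libraries at 0.6 to 4.57, called 524 genes. Voom with quality weights called 184. Values among the smallest p were a log2 difference of 1.55 for the membrane channel gene Ttyh2 (SE 0.27), 2.29 for Lyz2 (SE 0.47), 0.86 for the major vault protein Mvp, 1.11 for the surface antigen Ly6a, -1.30 for the small GTPase Rhov and -1.24 for Rnf10 (adjusted p from 0.251 to 0.262). Without control replicate 3, 4 genes rose and 1 fell. They were Prnp (1.26, SE 0.15, adjusted p = 0.009), Ttyh2 (1.24, adjusted p = 0.04), the myelin adhesion protein Mag (0.86, adjusted p = 0.034), Flywch1 (1.11, adjusted p = 0.019) and the heat shock chaperone Hspa1b (-0.91, adjusted p = 0.019).

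By list, 8 rose and 1 fell in the P301S effect at camera's preset correlation, and none passed with an estimated correlation, where the lowest adjusted p was 0.47. Disease-associated microglia rose with 17 of 20 measured members positive and a median log2 difference of 0.56 (camera adjusted p = 0.0013, adjusted p = 0.47 with an estimated correlation), and 7 members passed when adjusted over the list alone, among them Cst7 (2.93, SE 0.71) and the pattern receptor Clec7a (1.68, SE 0.53). Antigen presentation rose with a median of 0.90 (8 of 10 positive, adjusted p = 0.0015, and adjusted p = 0.47 with an estimated correlation). H2-Aa (2.12), H2-Ab1 (1.39), H2-K1 (1.38) and the immunoproteasome subunit Psmb8 (1.53) passed when adjusted over the list alone. Lysosome genes rose with a median of 0.46 (12 of 15 positive, adjusted p = 0.0015, and 0.47 with an estimated correlation), with Gusb at 1.05, Ctsz at 1.43 and Hexa at 0.88, and this list also passed fry (adjusted p = 0.031). Psap, at 2.28 (SE 0.97), owed that value in part to its level in control replicate 3.

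All 14 oligodendrocyte and myelin genes were positive, with a median of 0.30 (adjusted p = 0.0015, adjusted p = 0.47 with an estimated correlation), and the myelin genes Mog (1.01), Aspa (0.85) and Mal (0.47) passed when adjusted over the list alone. Pan-microglia and macrophage genes had a median of 0.56 (14 of 16 positive, adjusted p = 0.0015), complement genes 0.75 (6 of 7, adjusted p = 0.018), homeostatic microglia genes 0.30 (13 of 16, adjusted p = 0.016) and reactive astrocyte genes 0.35 (14 of 16, adjusted p = 0.042). With an estimated correlation the adjusted p was 0.62 for each of these 4 lists. Within them C1qc, a chain of the complement initiator, was at 1.49 (SE 0.46) and C1qa, another chain, at -0.51 (SE 0.68, 119 ± 19.7 RPKM against 283 ± 360 in controls). Fcer1g, an immune receptor adapter, was at 1.12 (SE 0.40), and the intermediate filament genes Vim and Gfap were at 0.80 and 0.31. Excitatory neuron genes fell with a median of -0.33 (9 of 14 negative, adjusted p = 0.016, and adjusted p = 0.62 with an estimated correlation), and the kinase gene Camk2a was at -0.96 (SE 0.30) and the calmodulin-binding gene Nrgn at -0.86 (SE 0.37).

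The remaining lists did not pass in the P301S effect (camera adjusted p from 0.084 to 0.97). Their median log2 differences were 0.44 for interferon response, 0.35 for inflammatory cytokine and NF-kB, 0.22 for astrocyte, 0.16 for oligodendrocyte precursor, 0.07 for inhibitory neuron, -0.03 for immediate early, 0.17 for endothelium and mural cell, -0.08 for heat shock and unfolded protein, 0.26 for cholesterol and lipid handling, 0.23 for mitochondrial respiratory chain and 0.07 for proliferation. Synapse genes had a median of 0.09 but a mean of -0.06 and a negative test direction. Among lists for other tissue, the medians were 0.75 for choroid plexus, 0.19 for meninges and fibroblast, 0.87 for striatum, -0.03 for hippocampus and 0.02 for blood, and 7 of 8 choroid plexus and 7 of 8 striatum genes were positive. Of the T cell list only Cd4 was measured, at 2.61 ± 1.5 RPKM in P301S+ TREM2+/+ mice and 1.1 ± 0.935 in controls (log2 difference 0.79, SE 0.42, adjusted p = 0.405). On list means per library, 9 lists reached the smallest possible exact permutation p of 0.029, which is 0.087 after adjustment. By share of reads, pan-microglia alone of these reached it (adjusted p = 0.26). Disease-associated microglia took 0.594 against 0.554% of reads (exact p = 0.69) and complement 0.0346 ± 0.0087 against 0.0407 ± 0.038% (p = 0.97). On list means, partial loss and complete against partial loss gave 0 lists under 0.05. Complete loss gave 1 (lowest adjusted p = 0.46), as did partial (0.35) and complete loss against control (0.41). Complement (medians 0.44, 0.55 and 0.62) was lost without P301S+ TREM2+/+ replicate 1, control replicate 1 or control replicate 4. Reactive astrocyte (0.20 to 0.45) was lost without any of these, P301S+ TREM2+/+ replicate 3 or control replicate 3. Homeostatic microglia was lost without control replicate 1 (0.24) or 4 (0.21), and pan-microglia without control replicate 1 (adjusted p = 0.051). The excitatory neuron call was lost without control replicate 1 (-0.32) or P301S+ TREM2+/+ replicate 1 (-0.24) or 3 (-0.30). Leaving out control replicate 1 left 4 of the 9 list calls, and leaving out control replicate 3 gave 13 (11 higher, 2 lower).

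**Figure D3:**
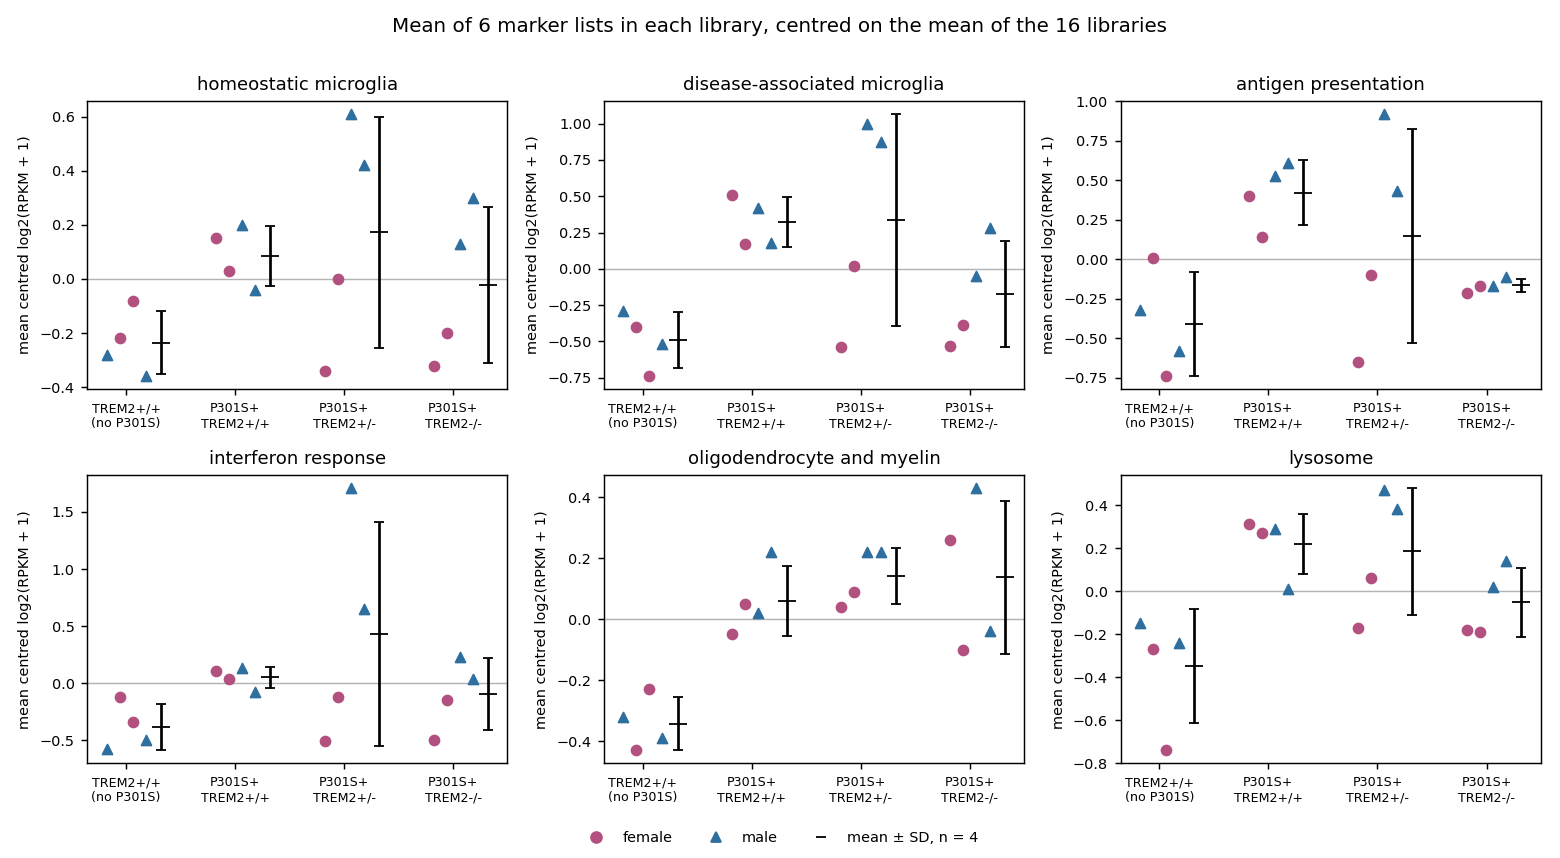
Mean log2(RPKM + 1) per library, centred per gene, of 6 lists (homeostatic microglia, disease-associated microglia, antigen presentation, interferon response, oligodendrocyte and myelin, lysosome), by genotype and sex with the mean ± SD of 4 mice. In the disease-associated microglia list the heterozygous females average -0.26 and the heterozygous males 0.93, against 0.34 and 0.30 in P301S+ TREM2+/+ females and males.

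Partial loss of Trem2 was tested by comparing heterozygotes with P301S+ TREM2+/+ mice. Interferon response genes stood higher in the heterozygotes and choroid plexus and striatum genes lower, while disease-associated microglia genes had a median difference of -0.01. None of these lists passed with an estimated correlation (lowest adjusted p = 0.72). The median of disease-associated microglia was -0.51 in females and 0.53 in males (2 mice per genotype and sex) and that of pan-microglia -0.70 and 0.65. These differences between the sexes passed at camera's preset correlation and not with an estimated one (adjusted p = 0.11 for each). The interferon median was -0.29 in females and 1.20 in males, and the call ended without heterozygote replicate 3 (median -0.05) or control replicate 3 (adjusted p = 0.053). It also ended without P301S+ TREM2+/+ replicate 3 (camera adjusted p = 0.055) or 4 (median 0.22, adjusted p = 0.15). Trem2 itself differed by -1.17 on the log2 scale (SE 0.43, 2.26-fold lower, limma adjusted p = 1) and Tyrobp by -0.37. Cst7 was at 8.96 ± 8.75 RPKM in heterozygotes and 9.72 ± 5.7 in P301S+ TREM2+/+ mice, and Clec7a at 4.75 ± 5.05 and 2.86 ± 1.59 (SD, n = 4 each; both genes singled out after their values were seen). Prnp was at 934 ± 163 and Mapt at 102 ± 6.37 RPKM in heterozygotes. No gene passed limma's test, with or without control replicate 3, 324 had an unadjusted p under 0.05, and limma-voom, array weights and quality weights called 0. Among the smallest p, the ADP-ribose hydrolase Oard1 was at 0.76 (SE 0.18), the transcription factor Sox21 at 0.62, the prostaglandin-degrading enzyme Hpgd at -0.75, and Fam219a at -1.16 (adjusted p = 1 for each).

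By list, 3 rose and 3 fell with partial loss, and none passed with an estimated correlation (lowest adjusted p = 0.72). Interferon response rose with 11 of 12 members positive and a median of 0.28 (camera adjusted p = 0.0026, adjusted p = 0.72 with an estimated correlation), with Ifit3 at 0.22 and Ifitm3 at -0.05. Inflammatory cytokine and NF-kB genes (8 of 8 positive, median 0.18, adjusted p = 0.028) and reactive astrocyte genes (13 of 16, median 0.28, adjusted p = 0.015) also rose, and cholesterol and lipid handling fell (median -0.21, adjusted p = 0.015), with the synthesis enzyme Hmgcs1 at -0.34. Choroid plexus fell with all 8 members negative (median -0.56, adjusted p = 0.0024) and so did striatum (8 negative, median -0.68, adjusted p = 0.0024). With an estimated correlation none of these lists had an adjusted p under 0.72. The interferon, NF-kB, reactive astrocyte, cholesterol and striatum calls ended when heterozygote replicate 3 was left out (medians -0.05, 0.11, 0.10, -0.17 and -0.23), the reactive astrocyte call also without replicate 4 (0.26). Only 1 list passed without P301S+ TREM2+/+ replicate 3 or without replicate 4, and 13 without heterozygote replicate 1. The choroid plexus call ended without P301S+ TREM2+/+ replicate 3 (median -0.31, camera adjusted p = 0.19). The striatum call ended without P301S+ TREM2+/+ replicate 4 (median -0.64, adjusted p = 0.15). No list rose and 2 fell without control replicate 3, choroid plexus and striatum (adjusted p = 0.033 for each), and with array weights none passed. After removal of control replicate 3 and both P301S+ TREM2+/+ females, 9 rose and 5 fell. Disease-associated microglia had a median of -0.01, homeostatic microglia 0.10, pan-microglia and macrophage -0.02, antigen presentation -0.29 and lysosome -0.07, none of which passed. The medians of disease-associated microglia, pan-microglia and lysosome genes turned to 0.28, 0.44 and 0.23 after that removal, and those of disease-associated microglia and pan-microglia to 0.23 and 0.24 without heterozygote replicate 1.

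Complete loss of Trem2 was tested by comparing knockouts with P301S+ TREM2+/+ mice. Trem2 fell, and as groups disease-associated microglia, pan-microglia, antigen presentation and choroid plexus genes stood lower in the knockouts. None of these lists passed with an estimated correlation (adjusted p of 0.86 or higher). The median of disease-associated microglia was -0.81 in females and -0.11 in males and that of pan-microglia -0.83 and 0.03. Both differences between the sexes passed at camera's preset correlation and not with an estimated one (adjusted p = 0.55 and 0.5). Trem2 differed by -3.17 on the log2 scale (SE 0.43, 9.02-fold lower, limma adjusted p = 0.04) and was the only gene past the threshold in this fit, with 1190 at an unadjusted p under 0.05. Other fits called 0 genes (limma-voom, and removal of control replicate 3 with both P301S+ TREM2+/+ females), 7 (only the genotypes compared), 123 (voom with quality weights) and 722 (array weights). Tyrobp was at 42.1 ± 22.1 RPKM in knockouts and 83.5 ± 27.4 in P301S+ TREM2+/+ mice (SD, n = 4 each; log2 difference -1.05, adjusted p = 0.439). Cst7 was at 3.05 ± 4.37 against 9.72 ± 5.7 RPKM (-1.81, adjusted p = 0.439), Clec7a at 0.478 ± 0.513 against 2.86 ± 1.59 (-1.37, adjusted p = 0.435) and Lyz2 at 6.28 ± 3.9 against 14.6 ± 5.18 (-1.18, adjusted p = 0.44), 3 genes singled out after their values were seen. Apoe, a lipid carrier of astrocytes and activated microglia, was at 563 ± 154 against 968 ± 186 RPKM (-0.80, SE 0.31). Prnp was at 907 ± 105 and Mapt at 102 ± 8.42 RPKM in knockouts. The neighbours of Trem2 were near or below 1 RPKM, Treml1 at 0.784 in P301S+ TREM2+/+ mice, 0.366 in heterozygotes, 0.25 in knockouts and 0.522 in controls, and neither Treml2 nor Treml4 averaged above 0.126 in any genotype.

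Among the smallest p of complete loss were Oard1 at 0.99 (SE 0.18, adjusted p = 0.414), the ubiquitin protease Usp5 at -1.08, Flywch1 at -1.49 (SE 0.31, adjusted p = 0.426), the splicing kinase Clk1 at 0.87, Rtn4ip1 at -0.72 and Mvp at -0.70. Oard1 (chromosome 17, 48410014 to 48417266) starts 55.9 kb from the end of Trem2 and was at 18.9 ± 2.53 RPKM in knockouts, 16 ± 1.68 in heterozygotes, 9.09 ± 1.76 in P301S+ TREM2+/+ mice and 9.32 ± 2.69 in controls. Flywch1, on the same chromosome (23752793 to 23771602, minus strand), was at 9.22 ± 0.879 RPKM in knockouts, 31.6 ± 8.03 in heterozygotes, 28 ± 5.09 in P301S+ TREM2+/+ mice and 20.8 ± 17.9 in controls. Without control replicate 3, which widens the shared spread but enters neither mean, 4 genes rose and 9 fell. They included Oard1 (0.99, adjusted p = 0.018), Flywch1 (-1.49, adjusted p = 6e-04), Trem2 (-3.17, adjusted p = 0.0043), the secreted C1q-like factor C1qtnf4 (-1.85, adjusted p = 0.0039) and the autophagosome protein Map1lc3a (-1.07). The call of Trem2 was lost when P301S+ TREM2+/+ replicate 1, 2 or 3, heterozygote replicate 2 or 4, any 1 of the 4 knockouts, or control replicate 1 or 2 was left out, with adjusted p from 0.06 to 0.3 and log2 differences from -3.01 to -3.40.

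By list, 4 fell with complete loss, and none passed with an estimated correlation (lowest adjusted p = 0.86). Disease-associated microglia fell with 4 of 20 members positive and a median of -0.45 (camera adjusted p = 0.02, adjusted p = 0.86 with an estimated correlation). Antigen presentation fell with a median of -0.46 (2 of 10 positive, adjusted p = 0.02), and the class II genes H2-Aa (-1.87) and H2-Ab1 (-1.44) and Psmb8 (-0.96) passed when adjusted over the list alone. Pan-microglia and macrophage genes fell with a median of -0.35 (2 of 16 positive, adjusted p = 0.046), with Fcer1g at -0.99 and the protease Ctss at -0.39, and choroid plexus genes with a median of -0.61 (1 of 8 positive, adjusted p = 0.046). With an estimated correlation the adjusted p of these lists was 0.86 or higher. The pan-microglia median turned to 0.08 after removal of control replicate 3 and both P301S+ TREM2+/+ females. Complement had a median of -0.46, lysosome -0.35, homeostatic microglia -0.14, interferon response -0.14, oligodendrocyte and myelin 0.15 and excitatory neuron 0.18, none of which passed. Without knockout replicate 3 the 4 called lists had medians of -0.39, -0.49, -0.33 and -0.52 in the order given above, and all missed the threshold (adjusted p = 0.053, 0.053, 0.07 and 0.15). Without P301S+ TREM2+/+ replicate 1 the medians were -0.30 for disease-associated microglia (adjusted p = 0.067) and -0.18 for pan-microglia (adjusted p = 0.18). The pan-microglia call was also lost without P301S+ TREM2+/+ replicate 2 (-0.28), knockout replicate 1 (-0.24) or control replicate 1 (adjusted p = 0.055). Choroid plexus was lost without P301S+ TREM2+/+ replicate 2 (-0.47) or 3 (-0.28), knockout replicate 2 (-0.72) or 4 (-0.51) or control replicate 1. Antigen presentation was lost without knockout replicate 4 (-0.52). Leaving out knockout replicate 4, P301S+ TREM2+/+ replicate 1 or control replicate 1 gave 2 lists, heterozygote replicate 1 gave 7 and P301S+ TREM2+/+ replicate 4 gave 8. Disease-associated microglia, antigen presentation and lysosome genes fell without control replicate 3 (adjusted p = 0.049 for each), and pan-microglia and choroid plexus did not pass (adjusted p = 0.12 for each).

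Complete and partial loss were compared directly, knockouts against heterozygotes. Complement, interferon, disease-associated and pan-microglial, astrocyte, lysosome and meningeal genes stood lower as groups in the knockouts, and immediate early and striatum genes higher, although no list passed with an estimated correlation (lowest adjusted p = 0.27). Interferon response fell with all 12 members negative (median -0.56, camera adjusted p = 9.4e-05, adjusted p = 0.32 with an estimated correlation) and complement with all 7 negative (median -0.55, adjusted p = 0.00025, and adjusted p = 0.27 with an estimated correlation). Disease-associated microglia fell with 2 of 20 positive and a median of -0.51 (adjusted p = 3.5e-05, and adjusted p = 0.27 with an estimated correlation), and homeostatic microglia did not pass (median -0.23, adjusted p = 0.12). The interferon median was -0.02 in females and -1.12 in males, and that of antigen presentation 0.07 and -0.90, differences between the sexes that passed at camera's preset correlation and not with an estimated one (adjusted p = 0.21 for each). C4b, a complement component, was at 2.44 ± 2.04 RPKM in knockouts and 6.79 ± 6.23 in heterozygotes, and Vim at 15.7 ± 1.9 and 32.4 ± 20.5 (SD, n = 4 each). Meninges and fibroblast genes fell (median -0.65, adjusted p = 0.00012), as did reactive astrocyte (-0.36, adjusted p = 0.00032), pan-microglia and macrophage (-0.40, adjusted p = 0.00028), astrocyte (-0.26, adjusted p = 0.0019), lysosome (-0.31, adjusted p = 0.0044), endothelium and mural cell (-0.16, adjusted p = 0.033), antigen presentation (-0.36, adjusted p = 0.046) and NF-kB genes (-0.31, adjusted p = 0.048). Immediate early genes rose with 11 of 12 positive (median 0.29, adjusted p = 0.0033), with Egr1 at 0.38 and Egr4 at 0.32, and striatum genes with 8 of 8 (median 0.52, adjusted p = 0.0055). Without heterozygote replicate 3 the calls of 7 lists ended, with medians of -0.21 for pan-microglia (adjusted p = 0.49), -0.11 for interferon response (adjusted p = 0.49), -0.13 for antigen presentation (adjusted p = 0.76) and -0.10 for NF-kB genes (adjusted p = 0.53). The others were at -0.11 for endothelium and mural cell, -0.23 for lysosome and -0.02 for striatum genes (adjusted p = 0.8). Striatum was also lost without knockout replicate 3 (0.21) or 4 (0.22) and immediate early without knockout replicate 4 (0.26). Antigen presentation was lost without P301S+ TREM2+/+ replicate 4, heterozygote replicate 4 or knockout replicate 3 or 4 (-0.34 to -0.39), and endothelium without heterozygote replicate 4 or knockout replicate 1 or 4 (-0.16 to -0.18). Among removals of a single mouse, the NF-kB call held only without P301S+ TREM2+/+ replicate 2, heterozygote replicate 1 or 4, knockout replicate 2 or control replicate 1 or 2.

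No single gene passed in that direct comparison (411 at an unadjusted p under 0.05, 0 called by limma-voom, 3 each with array weights and with quality weights, 1 with only the genotypes compared, smallest adjusted p = 1), and 35 rose and 4 fell after removal of control replicate 3 and both P301S+ TREM2+/+ females. Trem2 was 4-fold lower in knockouts than in heterozygotes on the log2(RPKM + 1) scale, and other values among the smallest p were -1.64 for Flywch1, 1.91 for the activity-induced synaptic protein Nptx2, 0.86 for C2cd5, 0.79 for the Wnt co-receptor Kremen1 and 1.05 for Klhl29. Tyrobp was at -0.67. Without control replicate 3, Flywch1 (-1.64, adjusted p = 0.00018) and C1qtnf4 (-1.61) fell, the second chosen after its values were seen. Leaving out heterozygote replicate 1 gave 17 lists in place of 13. Removal of control replicate 3 left 2 lists that rose and 8 that fell, and antigen presentation, endothelium and mural cell (adjusted p = 0.053 for each) and NF-kB genes (adjusted p = 0.13) did not pass.

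The departure of the heterozygotes from the midpoint of P301S+ TREM2+/+ mice and knockouts asks whether 1 lost allele has an intermediate effect. Interferon response lay above the midpoint in all 12 members (median 0.42, camera adjusted p = 1.2e-06, adjusted p = 0.25 with an estimated correlation), and without heterozygote replicate 3 the median was 0 (adjusted p = 0.55). Reactive astrocyte (median 0.30, adjusted p = 2.7e-05), complement (0.32, adjusted p = 0.0017), disease-associated microglia (0.27, adjusted p = 0.0014), pan-microglia and macrophage (0.21, adjusted p = 0.0081), NF-kB (0.30, adjusted p = 0.0026), astrocyte (0.10, adjusted p = 0.002) and meninges and fibroblast genes (0.42, adjusted p = 0.0014) also lay above it. Striatum genes lay below it in all 8 members (median -0.61, adjusted p = 3.2e-05), and so did choroid plexus (-0.38, adjusted p = 0.0081), cholesterol and lipid handling (-0.19, adjusted p = 0.002) and immediate early genes (-0.19, adjusted p = 0.019). None of the 12 lists passed with an estimated correlation (lowest adjusted p = 0.25). Trem2 lay 0.41 above the midpoint, the endotoxin co-receptor Cd14 0.50, Flywch1 0.90 and the DNA exonuclease Trex1 0.60, and the cholesterol synthesis enzyme Sqle was at -0.43. The midpoint was taken on the log2(RPKM + 1) scale, where a gene at the arithmetic mean of both homozygotes lies above it by construction. The sign of the Trem2 value therefore does not speak against an intermediate level. No gene passed (175 at an unadjusted p under 0.05, 0 by limma-voom), 1 did without control replicate 3 (Flywch1, 0.90), and without control replicate 3 8 lists lay above and 4 below. Leaving out heterozygote replicate 3 left 3 of the 12 calls, with medians of 0.15 for complement (adjusted p = 0.39), 0.12 for disease-associated microglia (adjusted p = 0.34), -0.07 for pan-microglia (adjusted p = 0.48) and 0.11 for NF-kB genes (adjusted p = 0.34). The other lost calls were at 0.18 for reactive astrocyte (adjusted p = 0.071), 0.09 for astrocyte, -0.08 for cholesterol and -0.12 for striatum genes (adjusted p = 0.55). Leaving out heterozygote replicate 4 left 6, with disease-associated and pan-microglia at 0.14, complement at 0.27, meninges at 0.23, choroid plexus at -0.31 and immediate early at -0.14. Pan-microglia was also lost without P301S+ TREM2+/+ replicate 3 (0.17) or 4 (0.11) or knockout replicate 1 (0.16). Choroid plexus was lost without P301S+ TREM2+/+ replicate 2 (-0.19) or 3 (-0.20), heterozygote replicate 1 (-0.10) or knockout replicate 1 (-0.22). Immediate early was lost without P301S+ TREM2+/+ replicate 4 (-0.10), heterozygote replicate 1 (-0.16) or knockout replicate 1 (-0.13) or 4 (-0.19).

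Both Trem2-deficient tau genotypes were also set against controls, from which they differ in the transgene and in Trem2 at once. In heterozygotes 11 lists rose, led by interferon response (all 12 positive, median 0.90, camera adjusted p = 6.1e-05), disease-associated microglia (19 of 20, median 0.77, adjusted p = 5.3e-05), complement (0.76, adjusted p = 0.0012) and reactive astrocyte (15 of 16, median 0.74, adjusted p = 6.1e-05). No list passed with an estimated correlation (lowest adjusted p = 0.21), while 7 of the 11 passed fry (adjusted p from 0.021 to 0.047), namely homeostatic and disease-associated microglia, NF-kB, reactive astrocyte, astrocyte, oligodendrocyte and myelin, and lysosome. The others were pan-microglia and macrophage (0.71), NF-kB (0.71), lysosome (0.47), antigen presentation (0.46), homeostatic microglia (0.43), oligodendrocyte and myelin (0.40) and astrocyte (0.36), and excitatory neuron genes fell (median -0.12, adjusted p = 0.018), a call lost without heterozygote replicate 4 (median 0.06), control replicate 1 (-0.08) or control replicate 2 (0.06). Pan-microglia was lost without heterozygote replicate 3 (median 0.40, adjusted p = 0.11). Antigen presentation was lost without heterozygote replicate 3 (0.32) or 4 (0.34) or control replicate 1 (0.49) or 4 (0.35), and astrocyte without heterozygote replicate 3 (0.35) or control replicate 4 (0.31). Removal of control replicate 3 gave 12 lists that rose and 2 that fell. In knockouts only oligodendrocyte and myelin rose (12 of 14 positive, median 0.42, adjusted p = 0.00021, and adjusted p = 0.6 with an estimated correlation). In it Mbp (0.95), Mog (1.22) and Mal (0.67) were among 6 that passed when adjusted over the list alone. This call was lost without control replicate 2 (median 0.37), and 5 lists passed without knockout replicate 1 and 3 without knockout replicate 2. Disease-associated microglia had a median of 0.46 and interferon response 0.32 in the knockouts and did not pass.

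Prnp differed from controls by 1.61 in heterozygotes (3.06-fold, adjusted p = 0.0868) and by 1.58 in knockouts (2.99-fold, adjusted p = 0.109), and no gene passed in either comparison (1153 and 1167 at an unadjusted p under 0.05, 1 and 0 by limma-voom, 23 and 4 with array weights, and 75 and 3 with quality weights). Trem2 was at -0.09 in heterozygotes and -2.09 in knockouts (adjusted p = 0.45). In heterozygotes Cd14 was at 0.93, Lyz2 at 2.06, the myelin protein Pmp22 at 0.99 and the synaptic organizer C1ql3 at -0.97, and in knockouts Oard1 was at 0.98, Mal at 0.67 and the GABA receptor subunit Gabra3 at -0.83. Without control replicate 3, Prnp passed in both (1.35, adjusted p = 0.0037, and 1.32, adjusted p = 0.005), with Flywch1 and Mag beside it in heterozygotes, and 8 lists rose and 4 fell in knockouts.

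**Figure D4:**
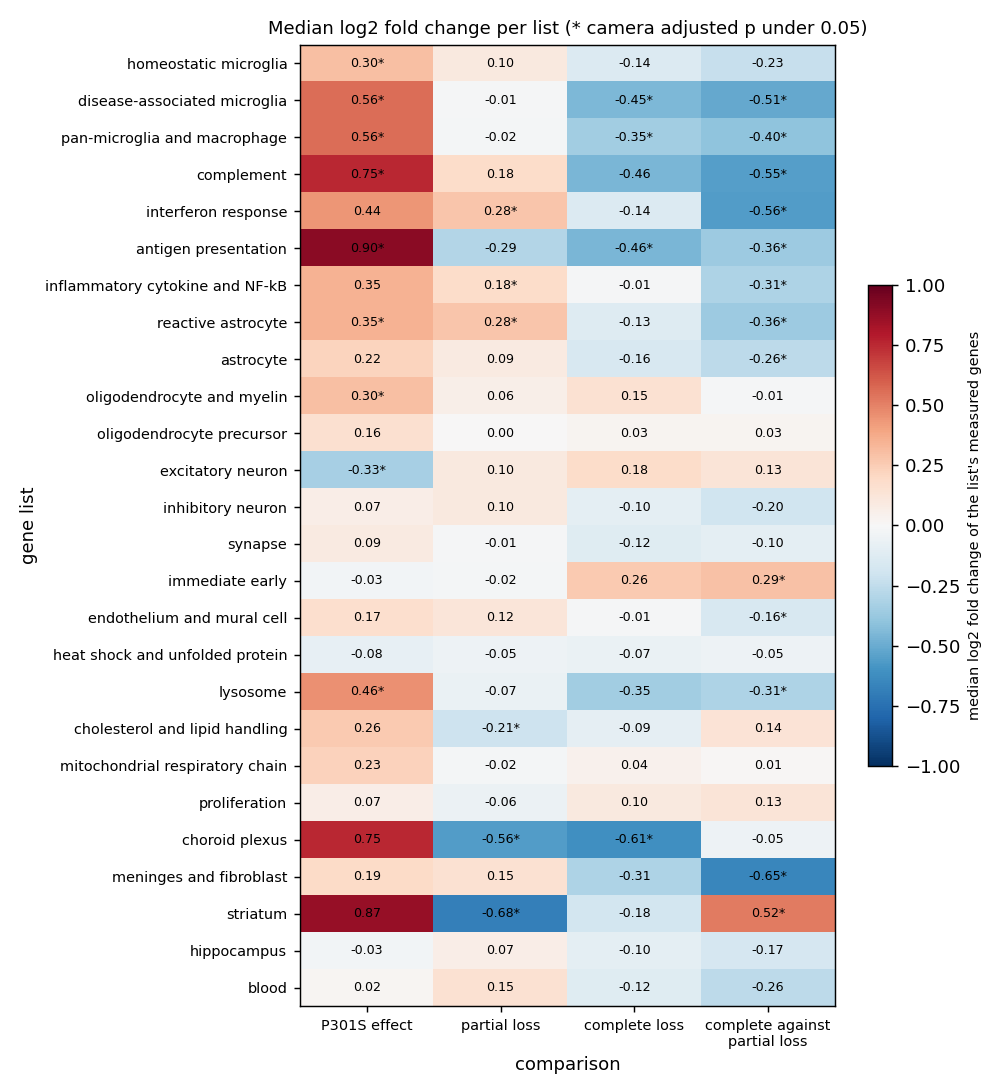
Median log2 fold change of each tested list in the P301S effect, partial loss, complete loss and complete against partial loss, with a star where the camera adjusted p is under 0.05. Interferon response has a median of 0.28 in partial loss and -0.56 in complete against partial loss, and disease-associated microglia 0.56 in the P301S effect and -0.45 in complete loss. Heterozygotes enter the first pair of values with opposite signs, and P301S+ TREM2+/+ mice the second. Chance in those shared libraries alone can therefore give medians of opposite sign.

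The sexes were compared through the interaction of genotype and sex, with 2 mice per sex and genotype. In the P301S effect only Gm10373, an unannotated gene model, differed (females minus males 4.08, SE 0.38, limma adjusted p = 0.0029), on 0 to 19 reads per library, and it was not called by limma-voom. The unadjusted p was under 0.05 for 1619 genes there, 778 in partial loss, 870 in complete loss and 240 in complete against partial loss, and no gene passed in the latter 3. Leaving out either control female leaves 1 mouse in that cell of sex and genotype. Control replicate 3 then adds nothing to the spread, and the gene counts rose except in complete against partial loss. The comparisons where they rose all use the P301S+ TREM2+/+ females, which lay apart on the second principal component (-45 and -41.3). These counts are therefore not given as differences between the sexes. Array weights gave 74, 203, 235 and 1 genes, in the order of comparisons above. In partial loss 11 lists differed between the sexes, led by pan-microglia and macrophage (females minus males, median -1.56), complement (-1.55) and interferon response (-1.53), and with an estimated correlation none passed (lowest adjusted p = 0.11). Mean log2 values of interferon response genes were -0.32 in heterozygous females and 1.18 in heterozygous males. Reactive astrocyte genes were at -0.18 and 0.80 in the same mice, and meninges and fibroblast genes at -0.26 and 0.70. Exchange of genotypes within each sex allows a smallest exact permutation p of 0.056 over 36 arrangements, which disease-associated microglia, interferon response, complement, homeostatic microglia, pan-microglia, lysosome and heat shock genes reached.

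Across the 12015 genes, which are not independent replicates, the fold changes of partial and complete loss correlated at 0.70 (covariance 0.065). Both share the P301S+ TREM2+/+ libraries, and simulated unchanged groups gave 0.50 (covariance 0.047). The simulation gave all libraries the same spread within a gene, which fixes this value. In the data, departures from the own genotype had an SD of 0.42 to 0.48 in the shared libraries. They were 0.26 to 0.37 in heterozygotes and 0.3 to 0.34 in knockouts. A wider spread in the shared libraries raises what sharing alone gives, so 0.70 against 0.50 does not show a common effect. With those libraries split so that none was shared, the correlation was 0.39 on average over 4 splits (range 0.32 to 0.47, covariance 0.045). Both P301S+ TREM2+/+ females lay far out on the second principal component (-45 and -41.3). Splits that place them on opposite sides leave that departure in both comparisons. The split value therefore cannot isolate a common effect of Trem2 loss. Without these females and control replicate 3 the correlation was 0.52, with the remaining P301S+ TREM2+/+ libraries shared. The P301S effect correlated at -0.36 with partial loss and -0.42 with complete loss, where the simulation gave -0.50 for each. Control replicate 3, with a departure SD of 1.28, enters the control mean of the P301S effect. The simulated value therefore does not measure what sharing gives in these data. The split values were -0.13 and -0.26. Without control replicate 3 the split values were -0.38 and -0.61. The departure shared by the P301S+ TREM2+/+ females limits these split values in the same way.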

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

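All tests that weigh an explanation, and the counts over other splits, were chosen after the results were seen, whereas the interaction tests between the sexes were planned.

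Control replicate 3 departed from the other libraries of its genotype by an SD of 1.28 log2 units across genes, against 0.26 to 0.57 for each other library, and the departure lowered Psap to 10.5 RPKM and raised small nucleolar RNA to 758.6 reads per 1e+06 reads (3970 reads). Shallow sequencing is argued against, because the libraries with fewer reads departed by at most 0.47, and GC content at transcript 3' ends explained only 7.1% of the variance of the departure. A library that took up more RNA without a poly(A) tail could raise small nucleolar RNA, but other small RNA genes were at 82.7 reads per 1e+06 there against 88.8 to 161.5 elsewhere, so this stays open. Positions of reads within transcripts were not analysed here, and no biological explanation was tested, since the other 3 controls share the genotype. Across genes, which are not independent, the departure correlated at -0.49 with complete loss, in which this library enters neither mean, and at -0.31 when only the P301S+ TREM2+/+ males were used. It also correlated at -0.37 with partial loss, -0.34 with complete against partial loss and 0.35 with P301S+ TREM2+/+ females minus males. The relation is therefore not particular to complete loss.

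Microglial lists split by sex in the heterozygotes, with disease-associated microglia at a mean of -0.26 in females and 0.93 in males, against 0.34 and 0.30 in P301S+ TREM2+/+ females and males (2 mice each), and knockouts went the same way (-0.53 and -0.39 in females, -0.05 and 0.28 in males). Meningeal tissue in the male samples may bring macrophage genes, and meninges and fibroblast genes were at 0.70 in the males and -0.26 in the females, which goes with it. However, 7 genes restricted to microglia of the brain tissue itself also lay higher in both heterozygous males, by 0.7 log2 units on average. In knockouts they were at 0.17 and 0.36 in males and -0.22 and -0.10 in females. These genes are members of the homeostatic microglia list, whose split (-0.17 in heterozygous females, 0.51 in males) had already been seen. They are therefore not separate evidence. Taken as genes that the meninges do not bring, they argue only against the meninges as the whole source of that list's split. For the other lists, and for a part of this one, the meninges stay open. Chance with 2 mice per sex cannot be told apart from a sex difference, because exchanging genotypes within each sex gave an exact p of 0.056, the smallest that 36 arrangements allow. Sex remains open as a biological explanation, as do litter and preparation order, which the labels do not give.

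Oard1, singled out after its values were seen, was at 14.9 to 18.5 RPKM in heterozygotes and 16.3 to 22.3 in knockouts, above the 6.89 to 11.2 of P301S+ TREM2+/+ mice and the 6.06 to 12.1 of controls. With the projection of each library on the departure of control replicate 3 as a covariate, Oard1 differed by 0.71 (SE 0.14) in partial loss. In complete loss it differed by 0.89 (SE 0.15, limma adjusted p = 0.0551). Without the covariate the differences were 0.76 and 0.99 (SE 0.18 each). The projection itself differed by only -0.07 in partial and -0.14 in complete loss, so the covariate could remove little. The test therefore cannot exclude the property that sets control replicate 3 apart as the source. Sequence of another strain that travels with the targeted allele could also follow the number of lost alleles, and the 61 tested genes within 5 Mb of Trem2 had a median test statistic at percentile 70.2 of random gene sets (19.6 within 2 Mb, 80.2 within 10 Mb), and at 89.7 without control replicate 3 (22.4 and 94.8). That test leaves it open, since genes without a strain variant would not move. An effect of Trem2 loss on Oard1, or of the targeted change on a gene 55.9 kb away, was not tested and stays open.

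Other single libraries lay far from the rest of their genotype, over 136 groups of 4 libraries, of which chance gives about 1 in 20. Heterozygote replicate 2 departed least from its genotype, with an SD of 0.26. Trem2 was at 3.75 RPKM in knockout replicate 4. Knockout replicate 1 had a list mean of -0.01 for oligodendrocyte precursor genes and 0.62 for choroid plexus genes. P301S+ TREM2+/+ replicate 4 had 0.01 for lysosome genes and heterozygote replicate 1 had -0.9 for blood genes. Control replicate 1 had -1.64 for striatum genes, and control replicate 3 had -0.41 for meninges and fibroblast and -0.55 for hippocampus genes. Of 49 named genes, 2 had control replicate 3 as the outlying control.

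Differences between the sexes in the genotype effect, given as the effect in females minus that in males, passed for 1 gene and for lists in 3 comparisons at camera's preset correlation. Gm10373 differed by 4.08 in the P301S effect. In partial loss the list medians were -0.83 for homeostatic microglia, -0.89 for disease-associated microglia, -1.56 for pan-microglia and macrophage, -1.55 for complement, -1.53 for interferon response, -0.54 for antigen presentation, -0.43 for reactive astrocyte, -0.57 for astrocyte, -0.74 for lysosome, 0.37 for cholesterol and lipid handling and 0.95 for striatum. In complete loss they were -0.38 for homeostatic microglia, -0.61 for disease-associated microglia, -0.87 for pan-microglia and macrophage, -1.16 for complement, -0.45 for interferon response, -0.64 for lysosome and -1.09 for striatum. In complete against partial loss they were 0.60 for disease-associated microglia, 0.66 for pan-microglia and macrophage, 0.65 for complement, 0.86 for interferon response, 1.05 for antigen presentation, 0.67 for reactive astrocyte, -0.27 for excitatory neuron, -0.22 for synapse, 1.01 for choroid plexus, 1.04 for meninges and fibroblast and -2.18 for striatum. With an estimated correlation the lowest adjusted p was 0.11, 0.5 and 0.21 in these 3 comparisons.

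Over the splits of the same libraries, the real one included, chance was not excluded for any count of lists. The same held for the count of 1 gene in complete loss, which 4 of 35 splits reached (highest other 1). The splits count whichever gene is called, so they do not test the fall of Trem2, whose knockout libraries all lay below every other library. A real count of 0 genes is reached by any split and decides nothing, as in 35 of 35 splits for the P301S effect (highest other 403), partial loss (0), complete against partial loss (0) and partial and complete loss against control (1 each), and in 100 of 100 drawn splits for the midpoint departure (1). The 403 genes came from the split that exchanges control replicate 3 with P301S+ TREM2+/+ replicate 4 and leaves the other libraries with their genotype, and no other split of that comparison called more than 1. The source of these calls was not tested. Array weights, which weight control replicate 3 at 0.04, gave 524 genes between the genotypes themselves. Leaving this library out gave 5, so its low weight alone does not account for 524. The weights of the other libraries ran from 0.6 to 4.57. For lists, the 9 of the P301S effect were reached in 3 of 35 splits (highest other 10), the 6 of partial loss in 18 (17), the 4 of complete loss in 14 (10), the 13 of complete against partial loss in 4 (17), the 12 of partial loss against control in 6 (18) and the 1 of complete loss against control in 24 (7). The 12 lists of the midpoint departure were reached in 16 of 100 splits (19).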

How the results depend on the processing

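The settings with pseudocounts, array weights, quality weights, hidden-structure covariates and the joint removal of 3 libraries were chosen after the data were seen; the others were fixed before. No paired analysis was possible because the labels number the mice consecutively and give no litter, batch or day. The DESeq2 and surrogate variable alternatives were not run, although the recovered reads would have allowed count models. Scaling by library size alone equals the main setting. Median-ratio size factors, no sex covariate and lists without shared members changed no count by over 1.5 times, and median-ratio factors moved the median of all genes by under 0.1 in each comparison (-0.085 at most). Depth limits the low genes most, with 2.55 M reads in the shallowest knockout, and without control replicate 3 the simulation recovered 68% (P301S effect) and 87% (complete loss) of genes changed by a log2 of 1, with 11 and 14 false calls. Except where a construction is named, the cause of a change was not tested.

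Gene counts changed as follows, in the order P301S effect, complete loss, complete against partial loss, midpoint departure, partial loss against control and complete loss against control. Array weights, which weighted control replicate 3 at 0.04 and the other libraries at 0.6 to 4.57, gave 524, 722, 3, 1, 23 and 4. Quality weights in voom gave 184, 123, 3, 1, 75 and 3. The first component of the residuals as a covariate gave 1965, 779, 3, 1, 2227 and 2734. It is drawn from the residuals of the same fit, so it narrows the spread in every comparison and moves no group mean. All these counts are therefore too liberal by construction. The 3 counts against controls also keep control replicate 3 in the control mean. For complete loss, leaving control replicate 3 out gave 13 genes. The projection on the departure of control replicate 3 gave 3, 3, 2, 1, 2 and 1. For complete loss, voom, no filter, genes outside the chromosome of Trem2 (which leaves Trem2 out) and the removal of control replicate 3 with both P301S+ TREM2+/+ females gave 0 genes, and only the genotypes compared gave 7. For complete against partial loss, that removal gave 39 and only the genotypes compared gave 1. For partial loss against control, voom and a threshold of 0.1 gave 1 each and that removal gave 5, and it gave 1 for complete loss against control. Genes that differed between the sexes numbered 74, 203, 235 and 1 with array weights in the P301S effect, partial loss, complete loss and complete against partial loss, 0 with voom in the P301S effect and 3 without a filter in partial loss.

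List counts fell to 0 in all 7 comparisons with an estimated correlation. For partial loss they were 0 with array weights, 2 with only the genotypes compared and 14 after the removal of control replicate 3 with both P301S+ TREM2+/+ females. For complete loss they were 2 with a pseudocount of 0.1, 2 with 0.5, 2 with the stricter filter and 7 at a threshold of 0.1. For complete loss against control they were 9 with array weights, 14 after that removal, 2 with voom, 4 without a filter and 5 with only the genotypes compared. The T cell list could be tested only without a filter and passed in no comparison (adjusted p from 0.1 to 0.99). The correlation of partial with complete loss was 0.39 with split libraries, 0.76 for genes above a mean RPKM of 10, 0.62 with voom and 0.52 after that removal. That of the P301S effect was -0.13 with partial and -0.26 with complete loss with split libraries, -0.70 and -0.85 with array weights, and -0.70 with complete loss after that removal. List medians that turned, among lists called in either setting, ranged over left-out mice from -0.22 to 0.23 for disease-associated microglia, -0.27 to 0.24 for pan-microglia and macrophage and -0.05 to 0.61 for interferon response in partial loss, from -0.02 to 0.96 for striatum in complete against partial loss and from -0.07 to 0.44 for pan-microglia and macrophage in the midpoint departure. Against control they ranged from -0.33 to 0.06 for excitatory neuron and -0.24 to 0.62 for striatum in partial loss and from -0.25 to 0.23 for hippocampus in complete loss. After that removal, medians turned to 0.28 for disease-associated microglia, 0.44 for pan-microglia and macrophage and 0.23 for lysosome in partial loss, 0.08 for pan-microglia and macrophage in complete loss and -0.26 for hippocampus in complete loss against control, which was -0.32 with array weights.

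Leaving out each mouse in turn gave 0 to 5 genes in the P301S effect, 0 to 13 in complete loss, 0 to 2 in complete against partial loss, 0 to 1 in the midpoint departure, 0 to 3 in partial and 0 to 1 in complete loss against control, each highest without control replicate 3, and 0 in partial loss. Lists ranged from 4 to 13, 1 to 13, 0 to 8, 6 to 17, 3 to 15, 9 to 14 and 0 to 12 in the 7 comparisons. Genes that differed between the sexes ranged from 1 to 5011 in the P301S effect (5011 without control replicate 2, which leaves control replicate 3 as the only control female), 0 to 383 in partial loss, 0 to 566 in complete loss and 0 to 1 in complete against partial loss. The correlations ranged from 0.57 to 0.80, from -0.66 to -0.17 and from -0.83 to -0.18. Over all settings, single genes kept their side of the threshold in 2417 results, passed it in 53 and lost it in 14, lists in 4872, 169 and 222 with 15 medians that turned, and list means per library in 3495, 24 and 45.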

Other observations

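The values here were looked at after the main results were seen, and none was planned. Some libraries held transcripts of genes known from olfactory and pituitary tissue, and their source was not tested. Omp, a marker of olfactory sensory neurons, was at 28.3 RPKM in P301S+ TREM2+/+ replicate 3, 33.8 in control replicate 3 and 17 in heterozygote replicate 4, and at most 1.85 in the other 13 libraries. S100a5, also an olfactory marker, was at 121, 69.9 and 89.5 RPKM in the same libraries and at most 4.57 elsewhere. The pituitary hormone genes Prl and Pomc were at 28.2 and 81 RPKM in P301S+ TREM2+/+ replicate 1. Ttr, the transthyretin gene of the choroid plexus, ranged from 65.8 to 1740 RPKM over the 16 libraries.

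Xist was at 0.4 RPKM (46 reads) in heterozygote replicate 3, a male, against at most 0.0879 RPKM (8 reads) in the other males and 2.84 to 6.68 in the females. The same library had the highest mean of the 7 microglia-restricted genes, at 0.71. Leaving it out ended list calls in partial loss, complete against partial loss and the midpoint departure, and a link to its Xist level was not tested. Usmg5, which encodes a small subunit of the mitochondrial ATP synthase, was at 9.53 RPKM (17 reads) in control replicate 3 and at 1110 to 2060 in the other libraries.

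Without control replicate 3, the pairing of P301S+ TREM2+/+ mice with heterozygotes against knockouts with controls, which no comparison of the design uses, gave 29 genes (23 higher, 6 lower) at a limma adjusted p under 0.05 and 2720 at an unadjusted p under 0.05. The pairing of both Trem2-intact genotypes against both deficient ones gave 2 and 936, and the remaining pairing 0 and 707. Because mice were numbered consecutively by genotype, the first of these pairings cannot be told apart from a preparation order.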
